A study of Equus caballus with 9 samples.

How the data were processed

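Polyadenylated RNA was measured by sequencing in 9 libraries of horse bone marrow-derived MSCs. The groups were undifferentiated cells (MSC), cells taken towards adipocytes (ADM) and cells taken towards chondrocytes (CDM), with 3 libraries each. Sample titles gave the group and the replicate number. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical.

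The deposited values are raw counts of reads per gene for each library, with no normalization. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.5c, HTSeq 1.99.2, DESeq2 3.16 and the horse genome build equCab3, without saying which step used which setting. The annotation release and the strand setting of the counting are not given in the sources used here. It is therefore not known whether reads from a gene and from an overlapping or antisense partner were kept apart. Genes that share sequence with a near-identical copy may have lost reads. Each file ended with 5 summary lines for reads assigned to no gene; these were kept out of library sizes and tests. They held 24.4% to 30.2% of all counted reads in 8 libraries and 36.4% in CDM replicate 2. The lines for low alignment quality and for unaligned reads were 0 in every library.

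The files held 30371 gene IDs without symbols, and 0 of them matched the gene table used here. No gene is therefore named by symbol, and no position in the genome is given. The 38 gene lists fixed before the data were examined could not be matched to any ID, so their tests were not run. The rule for named genes, also fixed before the data were examined, took genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the 2 groups' libraries, ordered by fold change. It also asked for a symbol, a condition that was dropped, and at most 2 IDs per direction are printed as having passed. Where no gene passed, the gene with the smallest p in each direction is given with its values. The parts of the rule that name set symbols, list members, genes called in both comparisons or each group's most abundant genes were not applied. Genes singled out in other ways are said to have been chosen after their values were seen.

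Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 3 groups, which left 13571, and libraries were scaled by TMM, a trimmed mean of ratios between libraries. The quasi-likelihood test was applied in 1 fit of all 9 libraries with a term per group and 6 residual degrees of freedom, 2-sided. Adjustment followed Benjamini and Hochberg over the genes tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change was taken from the change and its F statistic. Levels are in CPM, the usual unit of counts relative to the library total, after TMM scaling, and correlations between libraries are Pearson correlations across the tested genes of log2 CPM with a prior count of 2. Genes are not independent replicates, so these correlations carry no p-value of their own. The likeness of a group's libraries was instead ranked among all 84 sets of 3 of the 9 libraries, a one-sided exact test whose smallest p is 0.0119, adjusted over the 3 groups. A gene was counted as separated when every library of one group lay above every library of the other. Chance gives 10% of genes for 3 libraries against 3 if the libraries are exchangeable. Groups that differ in spread can pass that share without a difference of level. An exact test of single values for 3 libraries against 3 cannot give a p below 0.1. The ranking of sets of 3 libraries and the counts of separated genes were not in the plan fixed before the data were examined.

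The within-group pairs of libraries were compared by a chi-square of their counts over genes with at least 10 counts. It lay between 69.2 and 1988 per degree of freedom, so no pair agreed within sampling noise as a library deposited a second time would, and each was counted as 1 library. This does not show that they came from separate cultures. The procedure was tested on simulated counts drawn from the means, dispersions and library sizes of the 13571 tested genes, with 200 genes changed in each of 3 simulations. For ADM against MSC it recovered 0% of 2-fold, 20.7% of 4-fold, 56.0% of 8-fold and 77.3% of 16-fold changes. For CDM against MSC the shares were 0.667%, 10.7%, 47.3% and 75.3%, and for ADM against CDM 0%, 18.0%, 53.3% and 80.0%. Wrong calls numbered 3 of 234, 6 of 207 and 3 of 230. Every library of a gene was drawn with 1 shared dispersion, and only genes with a mean of at least 1 CPM were changed. In the real libraries the spread differed between groups, with a biological coefficient of variation of 0.263 in ADM, 0.599 in MSC and 0.749 in CDM. The shares recovered and wrongly called may therefore not hold for them.

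Gene counts ranged from 17260899 to 39331930 per library. Wilson intervals of 95% are given for a share in a single library and cover counting error only, since reads without molecular identifiers are not independent molecules. Comparisons of ADM and of CDM with the same MSC libraries share chance values, so their covariance was set beside 100 simulations of unchanged groups; 3 MSC libraries cannot be divided into parts of 2.

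Alternatives fixed before the data were examined were relative log expression and upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, robust estimation of the spread, only the groups compared, the replicate number as a block, thinning to the smallest library, a log2 fold change of at least 1, and leaving out each library of the groups compared. Alternatives chosen after seeing the data were leaving out each library of the third group, leaving out MSC replicate 3 and CDM replicate 2 together, limma 3.58.1 voom with a quality weight per library, and library totals as the only scaling.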

Results

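Gene expression was measured by RNA sequencing in MSCs, the stromal cells of bone marrow that can be grown in culture and turned into several connective tissue lineages. Undifferentiated MSC cultures were compared with cells differentiated towards adipocytes (ADM) and towards chondrocytes (CDM), with 3 libraries per group. Reads assigned to genes numbered 26581345, 26769259 and 37609071 in MSC replicates 1, 2 and 3, 39331930, 34325959 and 27625854 in the ADM replicates, and 31936658, 17260899 and 28064326 in the CDM replicates. Between 15665 and 17329 genes had at least 1 count in a library. Genes are given by the IDs in the files, which do not pair them with names.

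The transcript make-up of CDM replicate 2 differed from that of the other libraries. Its 10 most abundant genes held 56.2% of gene counts, against 12.1% to 29.9% elsewhere, where MSC replicate 3 had the highest share. A single gene, ENSECAG00000027689, chosen after its values were seen, held 36.8% of the counts of CDM replicate 2 (Wilson 95% interval 36.739% to 36.784%). In the other libraries it held 0.685% to 3.30%. CDM replicate 2 also had the largest share of reads assigned to no gene, 36.4%, and a TMM factor of 0.525 against 0.904 to 1.41 in the others. All comparisons that include CDM carry this library unless stated.

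**Figure D1:**
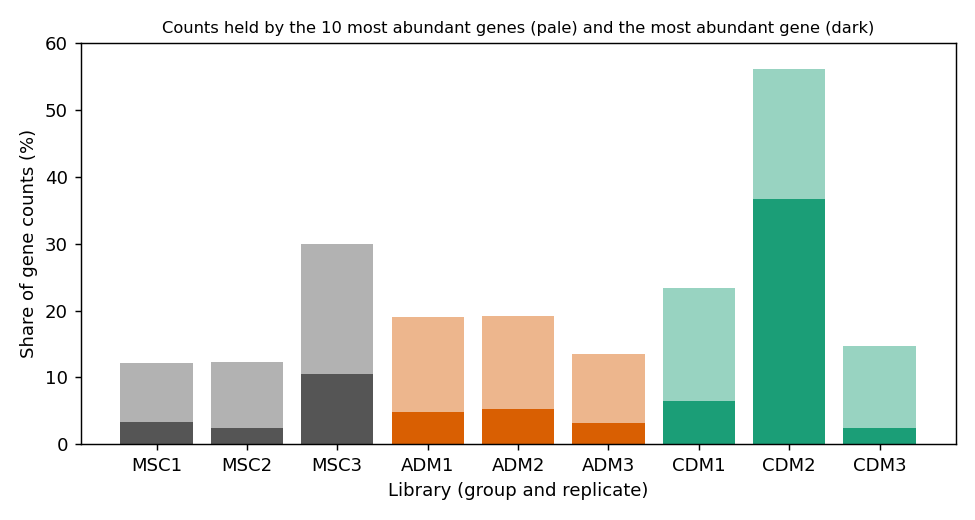
Share of gene counts (%) held by the most abundant gene (dark) and by the 10 most abundant genes (whole bar) in each of the 9 libraries; there are no error bars because each bar is 1 library. The 10 most abundant genes held 56.2% in CDM replicate 2 and at most 29.9% in any other library.

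The ADM libraries formed the tightest group. Their expression profiles correlated at 0.971 to 0.974 with each other (mean 0.973), higher than in any of the other 83 sets of 3 libraries (unplanned exact test, p = 0.0119, adjusted p = 0.0357 over 3 groups). The mean correlation was 0.885 among the MSC libraries (exact p = 0.560, adjusted p = 0.714) and 0.826 among the CDM libraries (exact p = 0.714, adjusted p = 0.714). The biological coefficient of variation estimated within each group was 0.263 in ADM, 0.599 in MSC and 0.749 in CDM. Several MSC and CDM libraries resembled a library of another group most. MSC replicate 1 was closest to CDM replicate 3 (0.944), MSC replicate 3 to CDM replicate 1 (0.918), and CDM replicate 1 to ADM replicate 3 (0.934). CDM replicate 2 reached at most 0.805, with CDM replicate 3. In the principal components of the 500 most variable genes, the first 3 components held 37.6%, 26.7% and 15.0% of the variance.

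**Figure D2:**
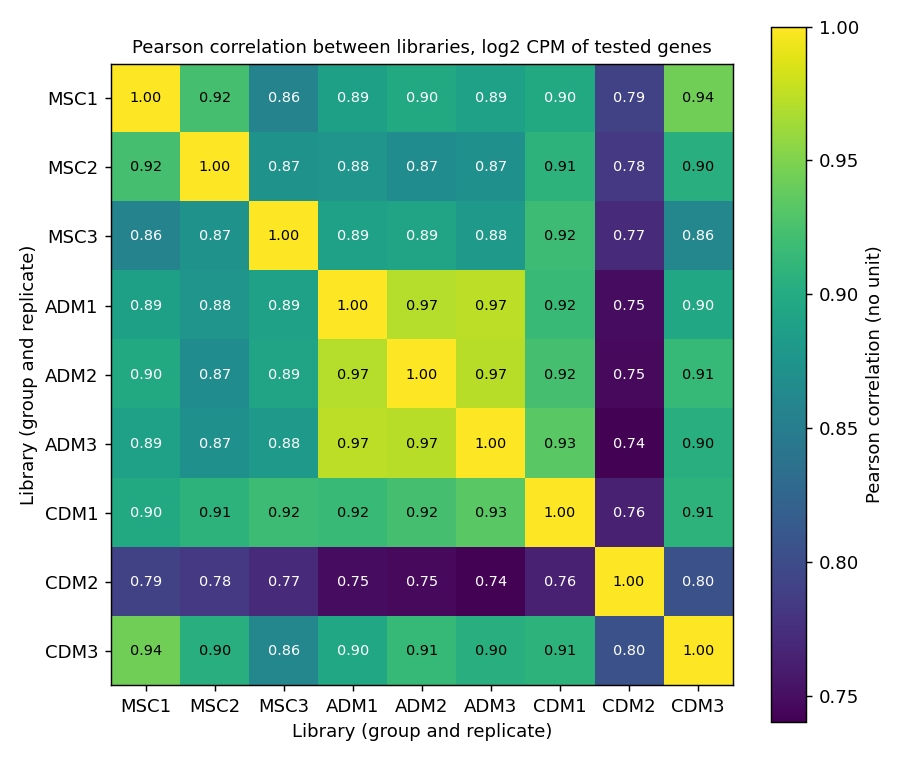
Pearson correlation (no unit) across tested genes of log2 CPM between each pair of the 9 libraries, with group and replicate on both axes and the value in each cell. ADM libraries correlated at 0.971 to 0.974 with each other, whereas CDM replicate 2 reached at most 0.805 with any library.

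The comparison of ADM with MSC asks how expression changed with adipogenic differentiation. In the fit of all 9 libraries, 2 genes rose and 2 fell. ENSECAG00000008063 rose 28.6-fold, from 1.09 ± 0.174 CPM (SD, n = 3) in MSC to 31.1 ± 5.46 CPM (SD, n = 3) in ADM. ENSECAG00000004544 rose 24.4-fold, from 0.427 ± 0.0895 to 10.5 ± 1.17 CPM (SD, n = 3 each). ENSECAG00000000157 fell from 29.1 ± 5.40 to 0.268 ± 0.279 CPM, with 812 to 1185 counts per MSC library and 2 to 20 per ADM library. ENSECAG00000011747 fell 14.3-fold, from 25.2 ± 8.65 to 1.76 ± 0.276 CPM (SD, n = 3 each). For all 4 genes, every ADM library lay on the same side of every MSC library, which the rule for named genes required. The log2 fold changes were 4.84 (SE 0.44), 4.61 (SE 0.45), -6.74 (SE 0.79) and -3.84 (SE 0.46), with edgeR quasi-likelihood adjusted p of 0.0131 for both genes that rose and 0.0421 for both that fell.

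Beyond these genes, many genes separated the ADM libraries from the others, although single genes did not pass. Of the 13571 genes tested, 2006 were higher and 1822 lower in every ADM library than in every MSC library. This is 28.2%, against 10% by chance if libraries are exchangeable. The ADM libraries spread less than the MSC libraries (biological coefficient of variation 0.263 against 0.599), which can raise the share without a difference of level. In edgeR, 1530 genes had an unadjusted p under 0.05, where 679 would be expected by chance. That count was 914, 1010 and 934 without ADM replicates 1, 2 and 3, where chance gives 702 to 707, and 2735 without CDM replicate 2. Relative to all 6 other libraries, 882 genes were higher and 700 lower in every ADM library. This total of 1582 was the most of any of the 84 sets of 3 libraries (exact p = 0.0119, adjusted p = 0.0357), and the next set, MSC replicate 1 with CDM replicates 2 and 3, had 1347. Such a rank cannot tell a change of level from the low spread within ADM, because tight libraries also raise the total. Without MSC replicate 3 and CDM replicate 2, a choice made after seeing the data, ADM still had the most of 35 sets, 3378 genes against 2990 (exact p = 0.0286). The number of genes passing depended on the fit: DESeq2 gave 261 higher and 331 lower, edgeR with only the ADM and MSC libraries 102 and 81, and edgeR without MSC replicate 3 and CDM replicate 2 gave 425 and 366. Leaving out any 1 ADM or MSC library left 0 higher genes and 0 or 1 lower, while leaving out CDM replicate 1 gave 16 and 7, CDM replicate 2 gave 97 and 76, and CDM replicate 3 gave 3 and 3.

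**Figure D3:**
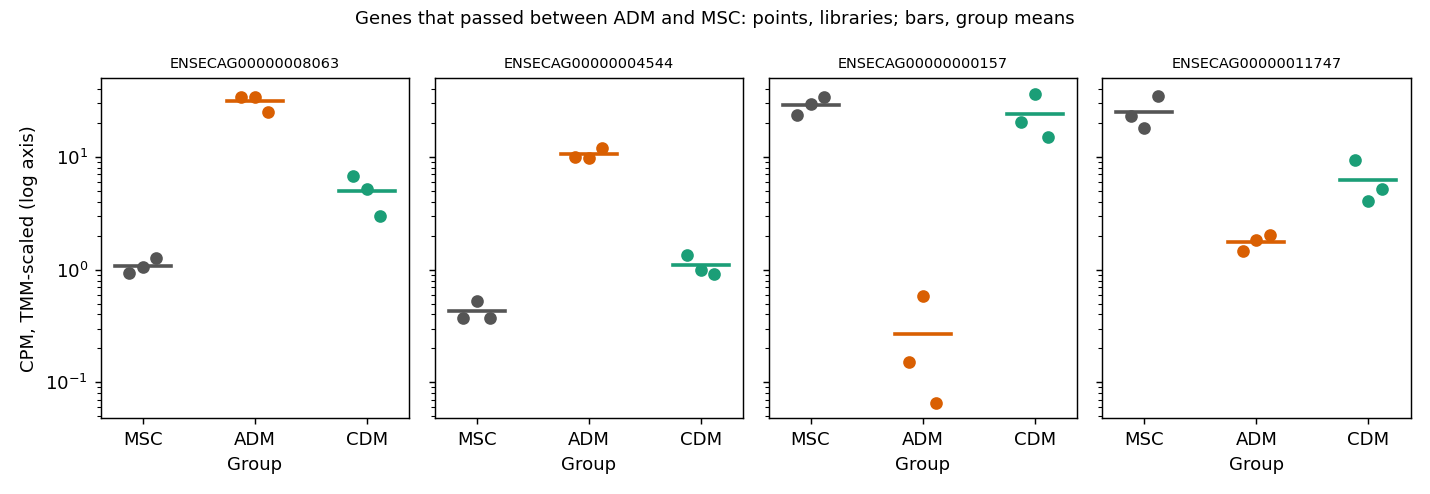
Level in TMM-scaled CPM (log axis) of the 4 genes that passed between ADM and MSC, with 1 point per library and a bar at the mean of each group of 3. Means in MSC and ADM were 1.09 and 31.1, 0.427 and 10.5, 29.1 and 0.268, and 25.2 and 1.76 CPM from left to right.

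The comparison of CDM with MSC asks how expression changed with chondrogenic differentiation. Few genes set the MSC and CDM libraries apart beyond the share that chance gives. The genes that passed between ADM and MSC had CDM means of 4.97 ± 1.90 CPM for ENSECAG00000008063 and 1.09 ± 0.231 CPM for ENSECAG00000004544, each above the MSC mean and below the ADM mean. ENSECAG00000011747, at 6.21 ± 2.75 CPM, also lay between its MSC and ADM means, and ENSECAG00000000157, at 23.9 CPM (range 14.95 to 36.2), was near its MSC mean (SD or range, n = 3 in each case). The genes with the smallest p in this comparison, picked by it after the test, were ENSECAG00000039617 and ENSECAG00000015144. ENSECAG00000039617 was at 5.28 ± 5.55 CPM in CDM and 6.47 ± 4.50 in ADM, against 0.0666 ± 0.0452 in MSC, where each library had 1 to 4 counts. ENSECAG00000015144 was at 18.1 ± 8.21 CPM in CDM and 20.98 ± 2.14 in ADM, against 101.9 ± 34.2 in MSC (SD, n = 3 each). None of these differences between CDM and MSC passed in edgeR, where the adjusted p was 0.448 for 5 of the genes and 0.871 for ENSECAG00000000157. Over all genes, 569 were higher and 869 lower in every CDM library than in every MSC library, or 10.6% against 10% by chance. This total of 1438 was 2048 with library totals as the only scaling, an alternative chosen after seeing the data.

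In edgeR, 0 genes passed between CDM and MSC in either direction, the smallest adjusted p was 0.448, and 1502 genes had an unadjusted p under 0.05, where 679 would be expected by chance. Other splits of the same libraries gave up to 2457 such genes, so the excess over 679 cannot be read as a difference between the groups. DESeq2 gave 46 higher and 37 lower, and CDM replicate 2 was the most extreme CDM library in 25 and 20 of these. The count at an unadjusted p under 0.05 was 544 in the edgeR fit of only the CDM and MSC libraries, where chance gives 659, 3075 without CDM replicate 1 and 818 without MSC replicate 2, with 0 genes passing in each case.

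The comparison of ADM with CDM tests the difference between the lineages, and with it the difference of their changes relative to MSC. ADM and CDM were separated for many genes, 2124 higher and 1500 lower in every ADM library than in every CDM library. This is 26.7%, against 10% by chance if libraries are exchangeable. The ADM libraries spread less than the CDM libraries (biological coefficient of variation 0.263 against 0.749), which can raise the share without a difference of level. The share alone therefore does not show that the lineages differed. The gene with the smallest p in each direction was ENSECAG00000004544, higher in ADM at 10.5 ± 1.17 against 1.09 ± 0.231 CPM, and ENSECAG00000000157, lower in ADM at 0.268 ± 0.279 against 23.9 CPM (range 14.95 to 36.2; SD or range, n = 3 each). Their log2 differences were 3.27 (SE 0.42) and -6.45 (SE 0.78), and neither passed (edgeR adjusted p = 0.141 for both). In edgeR 0 genes passed, and 2583 had an unadjusted p under 0.05, where 679 would be expected by chance. That count was 1258, 1444 and 1495 without ADM replicates 1, 2 and 3, and 4197 without CDM replicate 1. DESeq2 gave 351 higher and 579 lower, and edgeR without MSC replicate 3 and CDM replicate 2 gave 22 and 25. Voom with library weights, chosen after seeing the data, gave 697 higher and 450 lower, so the balance of directions depended on the test.

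Changes of ADM and CDM relative to MSC were compared across genes. At an unadjusted p under 0.05, 134 genes were higher in both, against 43.1 for independent lists, 142 were lower in both, against 40.8, and 24 moved in opposite directions, against 85.5. Part or all of this excess may come from the MSC libraries that both comparisons share, since these counts were not simulated for unchanged groups. The share of genes that changed in the same direction was 55.6%, below the mean of 66.4% in simulated unchanged groups against shared MSC libraries. For this share and the values that follow, changes were differences between group means of log2 CPM with a prior count of 2. These differences correlated at 0.310 across genes, below the 0.493 of those simulations. Their covariance was 0.255, within the simulated range of 0.251 to 0.291 (mean 0.266). The simulations drew genes independently and every library of a gene with 1 shared dispersion, whereas the spread differed between groups. Over 20 simulations the simulated mean was 0.268, and 0.197 without CDM replicate 2, although the MSC libraries were the same. Simulated values here and in the fits below therefore cannot decide whether ADM and CDM shared changes beyond the shared controls. The difference between observed and simulated covariance was 0.0882 without MSC replicate 1, 0.179 without MSC replicate 3 and 0.207 without CDM replicate 2, each above the range of 20 simulations made for that fit, and -0.136 without MSC replicate 2. No gene passed in both comparisons in edgeR, and DESeq2 gave 41 that passed in the same direction in both.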

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

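The tests of removing abundant genes and of thinning in CDM replicate 2 were set before their results were seen; the other tests in this part were chosen after the results they bear on had been seen.

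The HTSeq summary lines, which the comparisons do not use, were above the range of the 3 MSC libraries in CDM replicates 2 and 3, but not in CDM replicate 1. Reads in no annotated feature made up 24.4% in CDM replicate 2 and 23.3% in CDM replicate 3, against 17.7% to 22.1% in MSC and 16.9% in CDM replicate 1, the lowest of all 9 libraries. Ambiguous reads made up 4.47% in CDM replicate 2, against at most 1.74% in MSC, and reads with more than 1 alignment 7.49%, against at most 6.72%; both shares lay within or below these limits in CDM replicates 1 and 3.

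In 66 genes every ADM library lay above and every CDM library below all MSC libraries, and in 46 genes the order was the opposite. Chance gives 8.08 genes per order if libraries are exchangeable. The difference between the lineages was not tested for these genes as a set.

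CDM replicate 2 stood apart from the other 8 libraries. Without its 20 most abundant genes its highest correlation was 0.803, below the lowest correlation among the others (0.855). This cannot decide whether abundant genes were the cause, because each gene weighs equally in the correlation and 20 genes could hardly move it. Thinning the others to its remaining counts left their lowest correlation at 0.864, above its highest of 0.809. These thinned values argue against depth as the whole cause of its low correlation. A wrong label stays open: its highest correlation with an MSC or ADM library was 0.790, below the lowest among the other 8 (0.856), but so was its highest with a CDM library (0.805), so this value decides nothing. RNA of other cells or of lower quality stays open too: its ambiguous reads (4.469% against at most 1.741%) leave this undecided, because no marker list could be matched to the gene IDs. A true difference in how this culture differentiated was not tested, since the design gives no group for it.

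MSC and CDM libraries did not separate in the scaled data beyond the share chance gives, and a pair of label exchanges were looked at, both picked from these data. Exchanging MSC replicate 1 and CDM replicate 1 gave 2457 genes at an unadjusted p under 0.05, the most of the 10 splits (1502 as labelled, 1799 in the next), but 1993 without CDM replicate 2. Exchanging MSC replicate 3 and CDM replicate 3 gave 1786 with all libraries and 2391 without CDM replicate 2, the most of those 10 splits, with 261 genes passing against 0 as labelled. These exchanges cannot be told apart from each other or from differences between animals or cultures, which the labels do not record, because the best split changes with 1 library. Whether CDM replicate 2 hid a difference also stays open. Without it 1284 genes reached an unadjusted p under 0.05, and 0 passed. That count was 1502 with it and 818 to 3075 without each other MSC or CDM library. The covariance of the ADM and CDM changes without it was 0.404, above the simulated maximum of 0.210. This decides nothing, because the simulations used 1 dispersion for all groups and their mean fell from 0.268 to 0.197 without this library.

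Few genes passed between ADM and MSC in the fit of all 9 libraries. With only the ADM and MSC libraries in the fit, 183 genes passed instead of 4, so the spread of the CDM libraries in the shared estimate is a candidate cause. Leaving out CDM replicate 2 gave 173 genes and the next CDM library, CDM replicate 1, 23, so that 1 library may account for most of it. The common biological coefficient of variation was 0.573 with all libraries, 0.487 without CDM replicate 2 and 0.449 with ADM and MSC only. The choice of test also moved the count: with all 9 libraries in the fit, 592 genes passed in DESeq2 and 1073 in voom with library weights. No biological explanation was tested for the number of genes passing.

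Other splits of the libraries were counted for each comparison. For ADM against MSC the labelled split gave 4 genes and the highest other 0, with 1 of 10 splits as large. For CDM against MSC the labelled split gave 0 and the highest other 1, and for ADM against CDM both gave 0; a labelled count of 0 makes 10 of 10 splits as large in each, whatever the data. At an unadjusted p under 0.05, the labelled split and the highest other gave 1530 and 682 genes for ADM against MSC, 1502 and 2457 for CDM against MSC, and 2583 and 1512 for ADM against CDM. These splits are too few for a share under 0.05. Among 60 drawn splits into 3 groups of 3, 4 gave at least the 2230 genes that differed among the labelled groups at an unadjusted p under 0.05, the labelled split included, so by this count chance cannot be excluded. Of the 4 splits that kept the ADM libraries together, the labelled one included, 3 reached that number, and of the 56 that did not, 1 did, with 2279 genes. The highest other split kept the ADM libraries together and exchanged MSC replicate 1 with CDM replicate 1, and gave 3116 genes, with 48 passing against 2 as labelled. Only the count of genes passing was several times the labelled one, since the count at an unadjusted p under 0.05 was 3116 against 2230. Such a passing count may point to some structure of the samples, but this split is the highest of those drawn and no structure was tested.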

How the results depend on the processing

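Leaving out each library of the third group, leaving out MSC replicate 3 and CDM replicate 2 together, voom with library weights and library totals only were chosen after seeing the data. For ADM against MSC (2 higher and 2 lower), relative log expression factors, upper-quartile factors, robust estimation and a log2 fold change of at least 1 gave the same counts. No filter gave 20 higher and 21 lower, the stricter filter 4 and 2, thinning 2 and 0, library totals only 1 and 1, DESeq2 261 and 331, only the groups compared 102 and 81, voom with library weights 643 and 430, and the fit without MSC replicate 3 and CDM replicate 2 gave 425 and 366. Leaving out 1 library gave 0 to 97 higher and 0 to 76 lower; the highest were without CDM replicate 2. For CDM against MSC (0 and 0), DESeq2 gave 46 and 37 and every other alternative 0; genes separated between CDM and MSC numbered 1438, 1351 to 1674 under the other scalings, filters and thinning, and 2048 with library totals only. For ADM against CDM (0 and 0), DESeq2 gave 351 and 579, voom with library weights 697 and 450, no filter 0 and 1, and the fit without MSC replicate 3 and CDM replicate 2 gave 22 and 25; leaving out 1 library gave 0 higher and 0 to 1 lower, the 1 being without ADM replicate 2. Called the same way in ADM and CDM relative to MSC were 0 genes, and 41 in DESeq2. The observed minus simulated covariance of the changes, -0.0131 over 20 simulations, ranged from -0.136 without MSC replicate 2 to 0.207 without CDM replicate 2. The replicate block gave 0 higher and 0 lower in each comparison, with 1115, 583 and 1621 genes at an unadjusted p under 0.05 for ADM against MSC, CDM against MSC and ADM against CDM. Deviations from group means correlated at -0.306 to 0.012 for same numbers and -0.115 to 0.369 for others, but outliers may mask pairing. The 4 genes that passed between ADM and MSC reversed in 0 of 22 alternatives; ENSECAG00000008063 passed in 15, ENSECAG00000004544 in 14, ENSECAG00000000157 in 15 and ENSECAG00000011747 in 12. All 4 were among the genes passing in DESeq2, in the fit of only the groups compared, in voom and without CDM replicate 2. Relative log expression factors moved the median log2 difference of ADM and CDM to -0.14, and library totals only moved the medians to -0.26 for ADM against MSC, -0.45 for CDM against MSC and 0.19 for ADM against CDM. The cause of the differences between tools and filters was not tested. The gene list alternatives were not run, because no ID matched a symbol. On depth, thinning every library to 17260899 counts gave 2 higher and 0 lower: ENSECAG00000000157 and ENSECAG00000011747 had log2 fold changes of -6.49 and -3.84, against -6.74 and -3.84, and an adjusted p of 0.0558 in edgeR (range over alternatives 2.489e-19 to 0.261 and 8.029e-14 to 0.261). Simulated 2-fold changes were recovered in 0% of cases for ADM against MSC, so changes of that size were not detectable with the simulated spread.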

Other observations

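A block of 17 genes, chosen after seeing the data because each had at least 1000 CPM in CDM replicate 2 and at least 4-fold the level of every other library, held 57.5% of the gene counts of that library. In the other libraries the block held 1.16% to 5.53%, with the highest share in MSC replicate 1 and 4.19% in CDM replicate 3. The order of the 17 genes by level was similar in the other libraries, with Spearman correlations with CDM replicate 2 of 0.816 to 0.958 across genes, which are not independent replicates. CDM replicate 2 had 612 genes at least 4-fold above and 149 at least 4-fold below all other libraries, counting genes with at least 10 CPM in the higher. The next was MSC replicate 3, with 67 above and 13 below.

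ENSECAG00000013693, chosen after its values were seen, was the most abundant gene in every ADM library, in MSC replicate 3 and in CDM replicate 1. It was at 47194, 53718 and 29483 TMM-scaled CPM in the ADM libraries, 114840 in MSC replicate 3 and 72309 in CDM replicate 1. In MSC replicates 1 and 2 it was at 7857 and 5956 CPM, and in CDM replicates 2 and 3 at 1860 and 17512 CPM. Its levels within MSC and within CDM therefore spread more than its levels in ADM, and no comparison between groups passed for it (edgeR adjusted p = 0.999, 0.908 and 0.863 for ADM against MSC, CDM against MSC and ADM against CDM).

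In 214 genes every ADM and every CDM library lay above all MSC libraries, and in 284 genes below them, against 161.6 genes by chance in each direction. The total of 498 was reached by 14 of the 84 sets of 3 libraries (exact p = 0.167, adjusted p = 0.167), and the CDM libraries were apart from all others in 714 genes (exact p = 0.119, adjusted p = 0.167).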
